A study of Mus musculus with 16 samples.

How the data were processed

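The study measured tail DNA of 8 mice of 1 family on 16 Agilent 2-colour arrays. Each mouse shared its arrays with DNA of 1 reference male, in both dye orientations. Per the labels, the 2 channels of each array name the mouse or the reference and its dye. The 2 arrays of a mouse are a technical dye swap of the same 2 DNAs and were counted as 1 replicate, and the 6 progeny are separate animals.

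Per the file headers, the authors extracted spots with Agilent Feature Extraction 10.7.1.1 and mapped probes to mm9. Per the file headers, the deposited log10 ratio of each spot is red (Cy5) over green (Cy3). The deposited processed intensity of each channel is background-subtracted and dye-normalised by a linear factor, per the file headers, with no lowess term. Median spot and local background intensity are also deposited. The deposited value table holds log2 ratios. Set against the scanner values of the same spots, its columns correlated with a size between 0.99 and 1.00, run as reference over mouse in both orientations, and have medians from -0.01 to 0.02. Its values also differ from the scanner ratios, by an SD over probe spots between 0.00064 and 0.039 per array. It leaves 81 to 306 probe spots of an array blank, and the method behind the difference is not given in the sources used here.

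Each array had 973116 features, of which 966371 were probe spots and 6745 control spots. Control spots were left out, and 36 probe spots outside the placed chromosomes too. Spots marked as non-uniform or population outliers, 120 to 285 per array, were left out, and 0 spots were saturated. The log2 ratio of the processed signals was turned to mouse over reference by the dyes in the labels and centred on the autosomal median of the array, with no loess or quantile step. Spots of 1 probe were averaged, which left 950713 probes. The mean of the 2 orientations is the profile of a mouse. The share of spots well above background in both channels was between 91.6% and 99.3% per array, and the number of arrays limits the precision. The scans fall into 5 batches, with sire and dam in batch 1, progeny 1 and 2 in batch 2, progeny 3 and 4 in batches 3 and 4, and progeny 5 and 6 in batch 5.

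Regions were called with an interval score in the style of Agilent's aberration detection. Within a chromosome, the interval with the highest size of summed log2 ratio over the spread times the square root of the number of probes was taken, and the search was repeated on both sides. Calls needed a score of 6, 3 probes, a mean log2 of 0.25 in size and 1 sign in both orientations. Intervals were limited to 3000 probes and to autosomes. Calls of different mice that overlap by 1 base form a locus. A locus is a candidate new one when a progeny carries it and both parents are under 0.1 or of the opposite sign without a call. A parent above that limit, or with an opposite call, makes it unclear. As controls, the caller ran on the dye control profile and on the autosomal probes in 1 shuffled order that was the same for every array. Tested on simulated data, with 136 regions of each kind planted in shuffled profiles, the caller recovered 97.1% of 3-probe regions at 0.9 and 33.8% at 0.5. It recovered 98.5% of 10-probe regions at 0.5, 59.6% at 0.3, and 92.6% of 20-probe regions at 0.3. This recovery was measured on the mean profile without requiring 1 sign in both orientations, so it can be lower under the full rule.

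Single probes were tested with limma 3.58.1 in R 4.3.3 on the mouse profiles, as the mean of 6 progeny against 0 and as progeny minus parents, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tested on 50000 simulated probes, the fit of progeny against the reference recovered 36% of changes of 0.3, 86% of 0.5 and 100% of 0.9, with 7 false calls. The fit of progeny against parents recovered 30% of changes of 0.5 and 74% of 0.9, with 8 false calls. Each size was planted in 50 probes with independent normal noise. So large a share of changed probes eases the adjustment, so recovery in the data can be lower for both fits. In the data, 25 of the 74 probes of a chromosome 4 segment with a progeny mean of 0.67 were called against the reference. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures used matplotlib 3.10.9.

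Named loci follow a rule fixed before the data were examined. All loci of a class were taken if there were 10 or fewer, and otherwise the 10 with the highest size of mean log2 over carriers times the square root of the number of probes. Named probes are the 10 called ones with the largest mean and 1 sign in all 6 progeny. Loci of at least 30 probes were added after their values were seen. The limit lies above the longest call in shuffled order, but shuffling also breaks up runs along the genome that dye effects can make.

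The alternatives were normexp with an offset of 50, the deposited value table, loess within arrays and leaving out dim or marked probes. For the calls they were also a score of 8, 5 probes, a mean of 0.5, a running median over 1000 probes subtracted, 1 orientation at a time, 50% reciprocal overlap and an absence limit of 0.2. A limit of 0.3 was tried for single probes, and limma was also run with scan batch as a block and without each progeny. Normexp used median spot signals, since mean spot signals were not among the columns used here. Gene lists planned before the data were examined were not run and genes were not named, since the annotation at hand is of another genome build than mm9 and coordinates are not converted.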

Results

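Genomic DNA from the tails of 8 C57BL/6 mice of 1 family was measured by array comparative genomic hybridisation, in which a mouse and a reference DNA carry different dyes and compete for the same probes. The family holds 1 sire, 1 dam and 6 progeny, numbered 1 to 6. Each mouse was hybridised against the same reference male on 2 arrays, once with the mouse in Cy5 and once in Cy3, which makes 16 arrays and 1 profile per mouse. The study asks whether copy number changes appear in offspring after fathers lived under gamma rays of 0.05 mGy per day for 400 days. The series title places this family under that exposure, whereas its design text calls the sire of this family non-irradiated, so the exposure of this sire is not settled here. No family of another exposure was analysed here, and no effect of dose can be measured. The arrays carried 950622 autosomal probes, with a median distance of 2053 bp between neighbours on genome build mm9, and 68 X and 23 Y probes. Median signal over background noise ranged from 10.03 to 28.8 in green and from 18.9 to 46.3 in red. Progeny 1 had the lowest green value and the widest probe-to-probe spread, 0.22 on the log2 scale against 0.14 to 0.17 in the other 7 mice. All log2 ratios are mouse over reference, and each mouse is 1 animal, so errors at a locus are the SD of the 2 dye orientations or the SE over probes. Genes are not named, because the scanner files give probe names and mm9 coordinates alone and no annotation of that build was used here.

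The X chromosome gave a known copy ratio. In the dam the X probes averaged 0.88 ± 0.09 (SD of the 2 orientations), against -0.02 ± 0.02 in the sire, where 1 copy is set against 1 in the reference male. Progeny 4, 5 and 6 had X ratios of 0.90, 0.89 and 0.86, and their Y ratios were -1.46, -1.49 and -1.39. Progeny 1, 2 and 3 had X ratios of -0.03, 0.04 and 0.00 and Y ratios of -0.05, 0.10 and -0.15. The Y ratio of the dam was -1.26 ± 0.18, and that of the sire was -0.13 ± 0.15. The dye directions in the labels gave the sign that a female over a male should have on every array of the dam. With normexp background correction the X ratio of the dam was 0.50 ± 0.02.

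**Figure D1:**
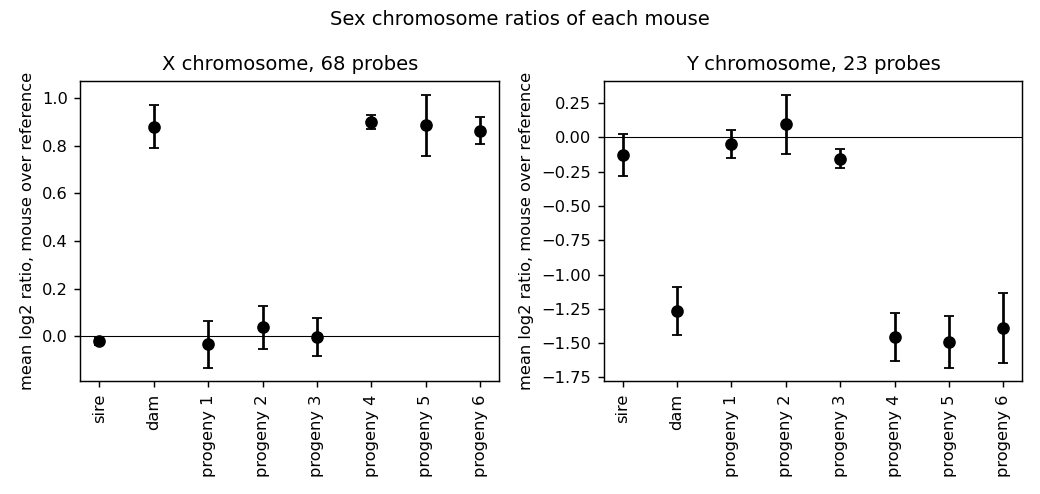
Mean log2 ratio, mouse over reference, of the 68 X probes (left) and 23 Y probes (right) in each mouse; bars are the SD of the 2 dye orientations. The dam and progeny 4, 5 and 6 lie between 0.86 and 0.90 on X, and the other 4 mice lie near 0.

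A segment of chromosome 4 was higher than the reference in all 8 mice, and it was the only locus called in every mouse. It runs from 101110482 to 101270535 on mm9, spans 160.1 kb and holds 74 probes, and the call began and ended at the same probes in each of the 8 mice. The mice did not share a level. The dam stood at 0.96 ± 0.02 (SD of the 2 orientations), progeny 3 at 0.97 ± 0.02 and progeny 4 at 0.92 ± 0.02. The sire stood at 0.51 ± 0.0039, and progeny 1, 2, 5 and 6 stood at 0.55 ± 0.013, 0.51 ± 0.00098, 0.55 ± 0.0047 and 0.56 ± 0.057. The SD between the 8 mice was 0.21, and the largest such SD in 9997 random windows of 74 probes off the segment was 0.11. Probes on both sides of the segment returned to values around 0, as the map of the segment shows. None of 10000 random autosomal windows of 74 probes lay as far from 0 in any mouse. Since the segment was found by a search for high scores, these windows describe its size and do not test it. Over the 6 progeny the segment averaged 0.67 ± 0.21 (SD, n = 6). A sign-flip test of these 6 values could give its smallest p alone, since the segment was picked by its calls in all 8 mice, and is not used. Calls in the segment were made in all 8 mice under each of the 11 settings in which the caller was run.

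**Figure D2:**
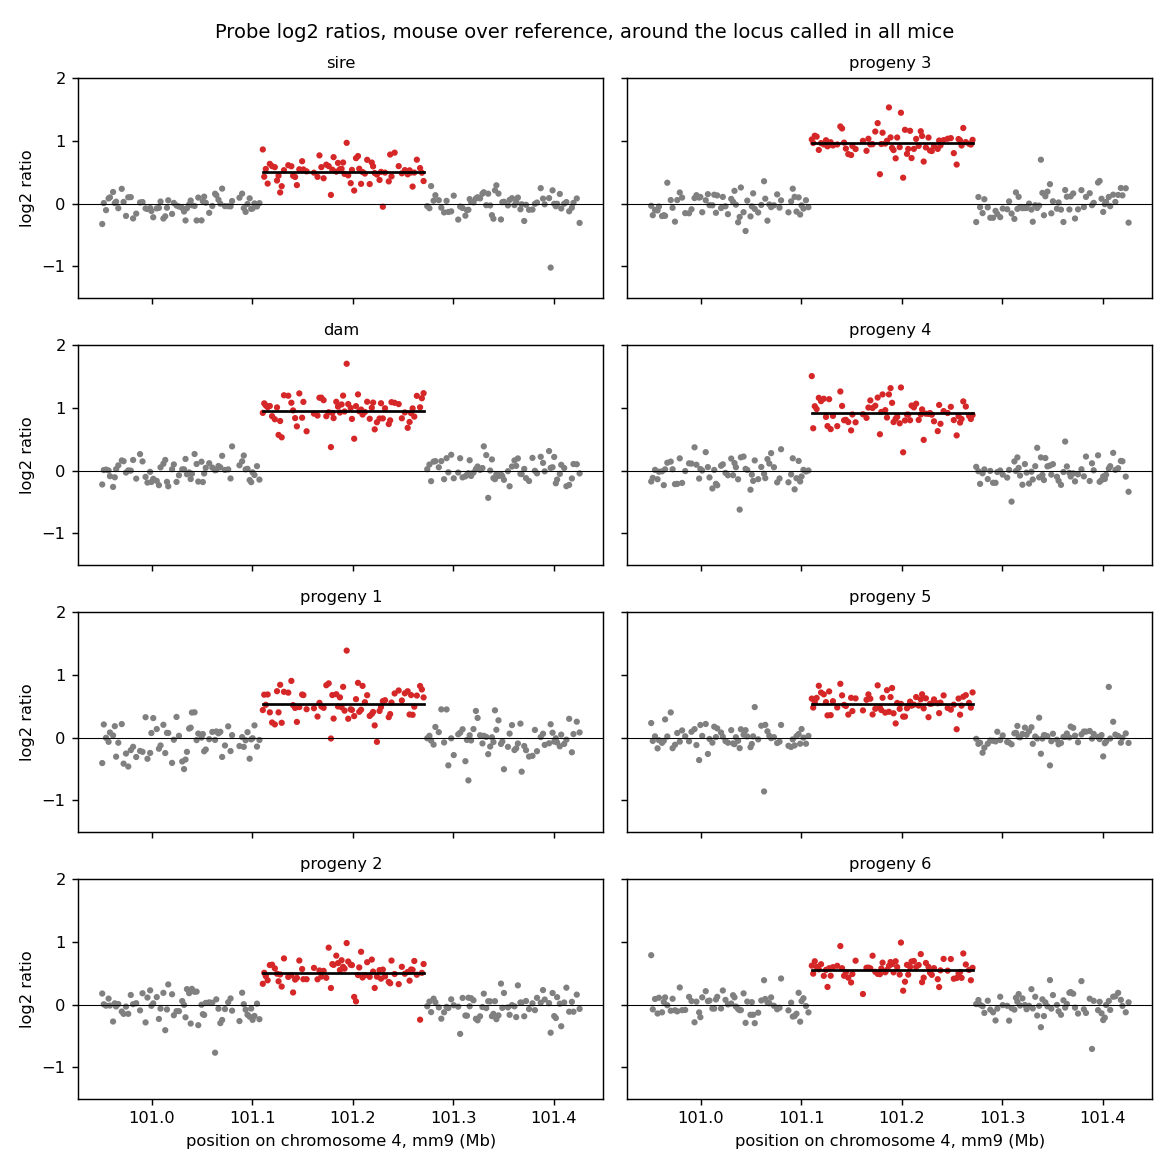
Log2 ratio, mouse over reference, of each probe against its mm9 position on chromosome 4 in the 8 mice. Red points are the 74 probes of the locus, grey points are flanking probes, and the black bar is the mean of the locus, between 0.51 and 0.97.

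Transmission within the family was examined through loci called with 1 sign in a parent and in at least 1 progeny. There were 32 such loci, 28 lower and 4 higher than the reference, and 27 of them held 3 probes. The longest was on chromosome 14 from 26696789 to 27120884, with 69 probes over 424.1 kb. It was lower in the dam, -0.32 ± 0.14 (SD of the 2 orientations), and in progeny 1, -0.31 ± 0.06, while the sire and progeny 2 to 6 lay between -0.02 and 0.03. In every mouse the ratio here was higher in Cy5 than in Cy3, for example 0.14 against -0.08 in progeny 4. On chromosome 8 a segment of 42 probes from 102125282 to 102244157 was higher in the dam at 0.29 ± 0.03. In progeny 4, 5 and 6 the same segment stood at 0.32 ± 0.02, 0.27 ± 0.02 and 0.27 ± 0.02. The other 4 mice lay between -0.06 and 0.02, with a 5-probe call of the opposite sign in the sire inside it. On the scale of the X ratio of the dam, 1 copy against 2 would give -0.88 and 3 against 2 would give 0.51. The carrier means of both long loci fall short of these levels. Chromosome 3 held a locus of 4 probes from 25417435 to 25444229 with a mean of -1.47 in the dam and progeny 4, 5 and 6, against -0.14 to 0.11 in the other mice. Of the 10 loci named by rank, 6 others had these same 4 carriers and held 3 probes each. They were on chromosome 6 at 104238274 to 104242812 (mean -1.30), chromosome 16 at 40849337 to 40854519 (-1.10) and chromosome 3 at 132546474 to 132549490 (-0.95). The remaining ones were on chromosome 7 at 141019208 to 141021785 (-0.92), chromosome 9 at 35855832 to 35862823 (-0.78) and chromosome 4 at 3892507 to 3895555 (-0.76). In each of these 6 the mean of the carriers fell to between -0.10 and 0.08 once the most extreme probe was left out. The 4 carriers are the mice with the X and Y ratios of females, with X between 0.86 and 0.90. At the lower loci of these carriers named by rank, the most extreme probe averaged between -4.07 and -2.03 over the carriers. The chromosome 3 locus of 4 probes kept -1.29 without that probe. Loss of 1 of 2 copies would give -0.88, so these values argue against such a loss passed on by the dam at these probes. For other forms of transmission, and at the chromosome 8 locus, transmission and a difference that goes with sex are not told apart. The last named locus, on chromosome 13 from 95703166 to 95707524, was called higher in the sire and progeny 1 at 0.74 and 0.81, while the other 6 mice lay between 0.19 and 0.50, and its mean fell to 0.15 without its most extreme probe. With probes in shuffled order, 33 loci fell in this class, so 32 does not exceed what unordered probes gave.

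**Figure D3:**
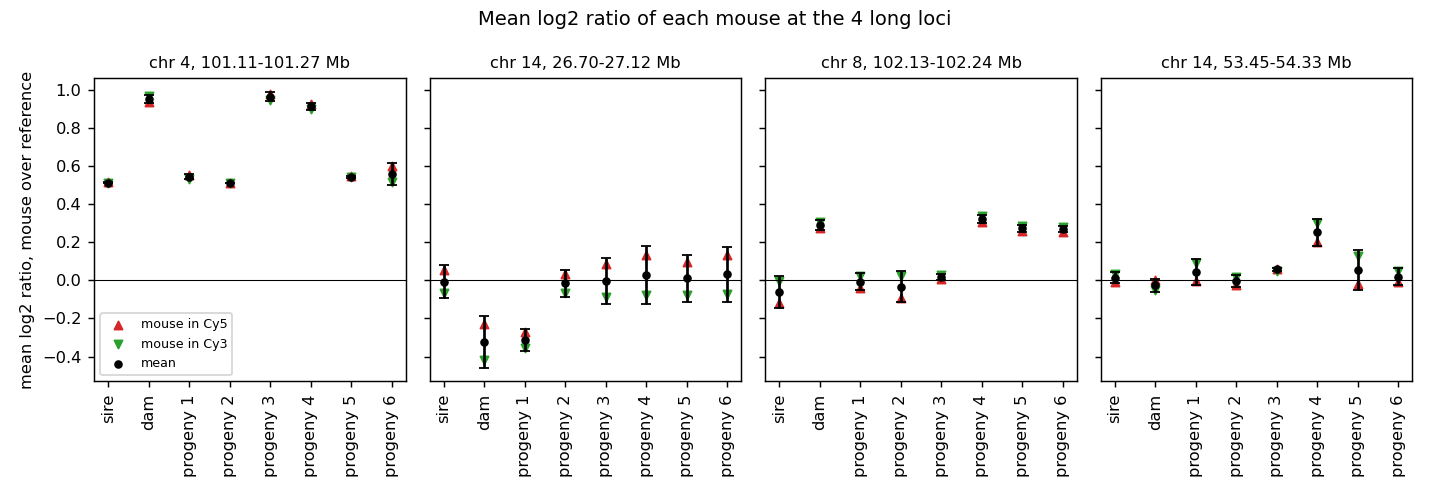
Mean log2 ratio, mouse over reference, of each mouse at the 4 loci of at least 30 probes. Black points are the means of the 2 dye orientations with their SD, triangles are the single orientations. Chromosome 4 is between 0.51 and 0.97 in all mice, and the chromosome 14 locus that starts at 53450514 stands at 0.25 in progeny 4.

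Candidate new regions, called in a progeny and absent from both parents, numbered 243, of which 145 were higher and 98 lower than the reference. Each had 1 carrier. Shuffled probe order gave 241. None of the 243 reached 30 probes, and 198 held 3. The 10 named by rank, with values on the carrier alone, were carried by progeny 1 (4 loci), progeny 2 (4 loci), progeny 3 (1 locus) and progeny 4 (1 locus). In progeny 2 they were lower, on chromosome 12 at 26587464 to 26591912 (-0.94), chromosome 11 at 49808802 to 49815342 (-0.84), chromosome 14 at 56138834 to 56142290 (-0.83) and chromosome 6 at 98942143 to 98947180 (-0.82). The array of progeny 2 in Cy5 carried most of each, for example -1.62 against -0.26 in Cy3 on chromosome 12. Of the 89 lower calls of progeny 2, 53.9% had their most extreme probe in the 7 tiles of the slide that were busiest for these calls and hold 4.83% of the probes. Tiles picked this way exceed their share in any set of calls. The 7 busiest tiles for the 84 higher calls of progeny 5 held 20.2% of them. In progeny 1, chromosome 11 at 80758787 to 80763462 stood at 0.90, chromosome 13 at 83598447 to 83604252 at 0.76 and chromosome 7 at 60716874 to 60720535 at 0.82. Chromosome 11 at 103865106 to 103869208 stood at -0.82 in progeny 1 as well. With progeny 1 in Cy3, the array of lowest green signal over noise (10.03), chromosome 11 at 80758787 stood at 1.34 against 0.46 in Cy5. Chromosome 7 stood at 1.24 against 0.40, and chromosome 11 at 103865106 at -1.07 against -0.56. The chromosome 13 locus went the other way, with 0.56 in Cy3 and 0.95 in Cy5. Progeny 3 was at 0.90 on chromosome 4 at 140282130 to 140287086, and progeny 4 was at 0.85 on chromosome 15 at 15924344 to 15931118. Without their most extreme probe 6 of the 10 fell below the 0.25 that a call needs in size. These were the loci of progeny 3 and 4 (0.16 each), those of progeny 1 on chromosomes 13 (0.24) and 7 (0.248) and those of progeny 2 at 49808802 on chromosome 11 (-0.15) and on chromosome 6 (-0.16).

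On chromosome 14, from 53450514 to 54332051, 87 probes over 881.5 kb averaged 0.25 ± 0.07 (SD of the 2 orientations, SE over probes 0.03) in progeny 4. That falls short of the 0.51 that 3 copies against 2 would give on the scale of the X ratio of the dam. The sire was at 0.01 ± 0.03 and the dam at -0.03 ± 0.04 over the same probes. The other 5 progeny were at 0.06 or below. None of 10000 random windows of 87 probes in progeny 4 was as far from 0. The interval was found by a search for the highest score in this mouse, so windows placed without a search cannot test it. Over the same probes 0.19% of the windows in progeny 5 and 3.29% in progeny 3 were as far from 0 as those mice. The segment was singled out after its values were seen. It was classed as unclear and not as candidate new, because a 3-probe call of the opposite sign in the dam lies inside it, beside a 3-probe call of progeny 3. The dye control had calls inside it in 3 progeny, at 53961688 to 54073297 in progeny 4 (-0.40) and 5 (-0.48) and at 53984133 to 53992339 in progeny 6 (-0.69). With a minimum of 30 probes, chosen after seeing the data, the segment was the 1 candidate new locus.

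Parents-only loci numbered 823, of which 755 were lower, against 792 with probes in shuffled order. All 10 named by rank were lower in the sire and held 3 probes. The first was on chromosome 13 at 48879149 to 48884300 (-1.27), followed by chromosome 8 at 92502923 to 92506806 (-1.14) and chromosome 6 at 30660756 to 30663932 (-1.09). The others were on chromosome 18 at 65416939 to 65420013 (-1.08), chromosome 5 at 149527972 to 149530823 (-1.06) and chromosome 4 at 20114238 to 20118773 (-1.05). Chromosome 1 at 72027364 to 72031331 stood at -1.01, and chromosome 19 at 32543676 to 32547131 at -0.997. Chromosome 14 at 65836561 to 65841202 and chromosome 6 at 54984115 to 54990651 were at -0.99 and -0.98. The array with the sire in Cy5 carried these loci, with means between -2.23 and -1.48, while the Cy3 array gave -0.49 to -0.05. Without dim probes and those with marked spots the chromosome 18 locus turned to 0.077.

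**Figure D4:**
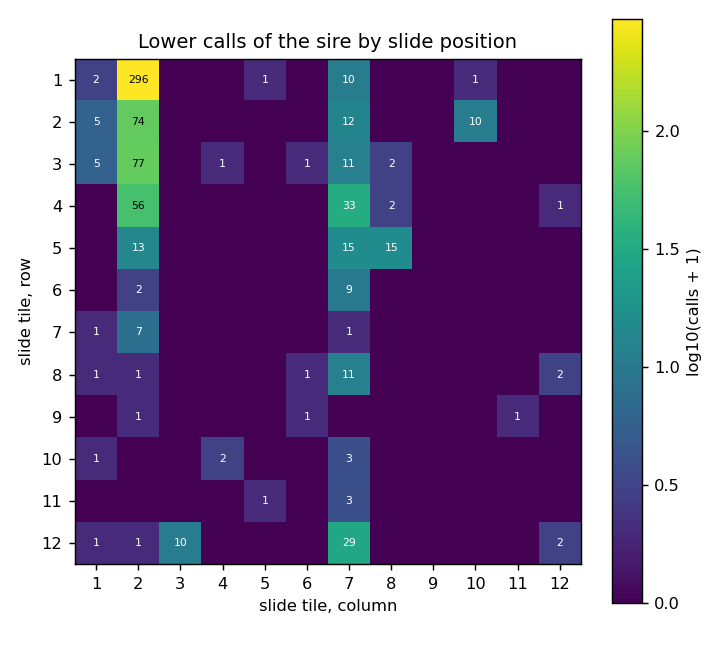
Number of lower calls of the sire whose most extreme probe lies in each tile of the slide, with slide rows and columns divided into 12 parts each. The busiest tile holds 296 of the 735 calls.

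Over all mice 1337 regions were called, 336 higher and 1001 lower, and 1119 of them held 3 probes. The same caller found 1335 regions in shuffled probe order and 679 in the dye control, the difference of the orientations divided by 2, in which DNA differences cancel. The sire had 784 calls and the dam 80, and progeny 1 to 6 had 20, 121, 59, 76, 131 and 66. In shuffled order these mice gave 742, 85, 24, 135, 57, 77, 145 and 70. The longest call in shuffled order held 22 probes. Calls of at least 10 probes numbered 30 in genome order and 64 in the dye control. Dye effects remain in the dye control and, where alike on both arrays, cancel in the mean of the orientations. The 64 therefore cannot tell how many of the 30 dye effects made. Progeny averaged 78.8 ± 41.3 calls (SD, n = 6) and the 2 parents 432, a difference of -353.2 with p = 0.107 in an exact two-sided permutation test over 28 arrangements, whose smallest p is 0.0357. With the mouse in Cy3 alone the difference turned to 15.0 (exact permutation p = 0.607). Without the sire, which holds 735 of the 1001 lower calls, the total was 553, with 287 higher and 266 lower, and progeny minus dam was -1.17.

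**Figure D5:**
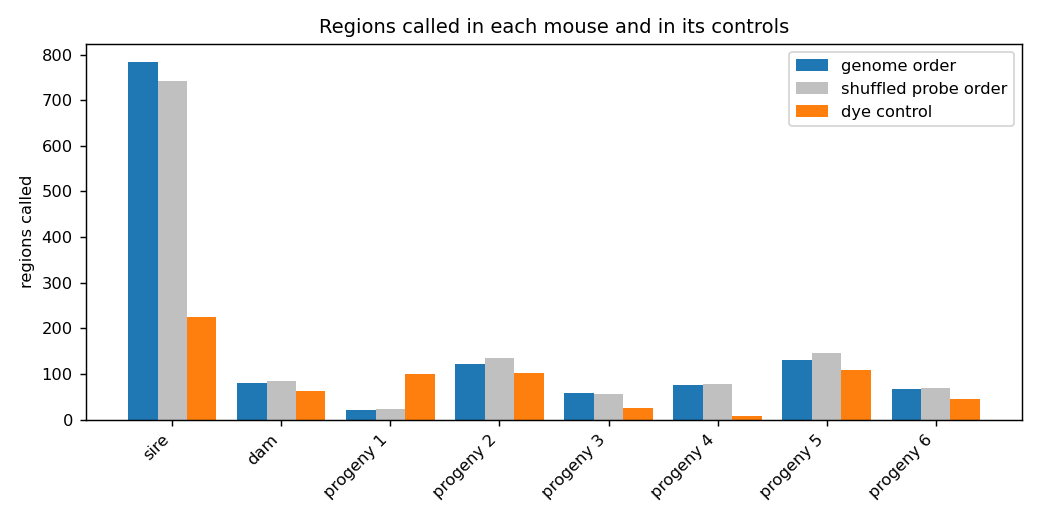
Number of regions called in each mouse in genome order (blue), in shuffled probe order (grey) and in the dye control (orange). The sire has 784 calls in genome order and 742 in shuffled order, and the numbers of the other mice also lie close to their shuffled ones.

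The study selected probes that deviate in both dye orientations. Past 0.5 in both orientations with 1 sign, 24149 probe-by-mouse values were found on the autosomes, 14883 higher and 9266 lower. The excess of higher values depended on the scaling, with 11522 higher and 11957 lower after loess within arrays and 927 higher and 1646 lower with normexp. The planned control, opposite signs in the 2 orientations, gave 74367. Dye effects alike on both arrays push a probe to opposite signs, so this count is no estimate of false values among the 24149. Progeny 1 held 9921 of the values, and without it 14228 remained. Single probes past the limit in 5 or more mice with higher ratios numbered 30, and 29 of them lie in the chromosome 4 segment. Arrays of 1 mouse in opposite orientations had correlations across probes from -0.37 to 0.02, and arrays of different mice in 1 orientation from 0.03 to 0.64.

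Against the reference, 26 of 950187 autosomal probes differed in the 6 progeny by limma at an adjusted p of 0.05, and 82354 had an unadjusted p under 0.05. Of these 26, 25 were higher and all 25 lie in the chromosome 4 segment, with means from 0.61 to 0.95. The largest of them was probe A_53_P138684 at 101138898 to 101138957, at 0.95 ± 0.09 (SE; adjusted p = 0.0402, limma), higher in 6 of 6 progeny. Probe A_67_P05336765 at 101176044 to 101176103 stood at 0.93 ± 0.09 (adjusted p = 0.0402, limma), and A_53_P105510 at 101261239 to 101261298 at 0.83 ± 0.09 (adjusted p = 0.0485, limma). The other 6 probes named by rank in this segment, A_67_P00943893, A_67_P00943781, A_67_P05336856, A_67_P05336931, A_67_P00944040 and A_67_P05336983, lay between 0.75 and 0.81. The 1 lower probe, A_67_P08537458 on chromosome 16 at 24886071 to 24886130, stood at -1.12 ± 0.09 (adjusted p = 0.0315, limma) and was lower in 6 of 6 progeny. At this probe the sire was at -0.47 and the dam at 0.82. The reference is 1 animal and its own spread is outside the test. Leaving out progeny 2, 3, 4, 5 or 6 left 0 called probes by limma in each case, leaving out progeny 1 gave 55, and with scan batch as a random block 7 were called.

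Between progeny and parents limma called 0 of 950016 probes at an adjusted p of 0.05, and 43836 had an unadjusted p under 0.05, which is 4.61%. Progeny and parents share no scan batch, so batch and generation cannot be told apart in this comparison. The chromosome 4 segment averaged 0.67 in the progeny, between 0.51 in the sire and 0.96 in the dam. Without the dam 1861 probes were called, 1838 of them higher in the progeny than in the sire, where the lone sire is assumed to vary like the progeny.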

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

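All tests of explanations in this part were chosen after the results were seen. In 48 groups of 6 progeny values, 11 had an animal far from the others by the gap to its neighbour over the range, and chance gives such an animal in about 1 in 20 groups.

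Of the 11, 8 are loci named as candidate new, which were selected because 1 progeny differs. Progeny 2 was at -0.94 on chromosome 12 at 26587464, -0.84 on chromosome 11 at 49808802 and -0.82 on chromosome 6 at 98942143. Progeny 1 was at 0.90 on chromosome 11 at 80758787, 0.76 on chromosome 13 at 83598447, -0.82 on chromosome 11 at 103865106 and 0.82 on chromosome 7 at 60716874. Progeny 3 was at 0.90 on chromosome 4 at 140282130.

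Progeny 1 had 9921 probe values past the limit in both dye orientations, and the next animal had 3694. At the chromosome 14 locus that starts at 26696789, progeny 1 was at -0.31 and the nearest other progeny at -0.02. At the chromosome 14 locus that starts at 53450514, progeny 4 was at 0.25 and the nearest other progeny at 0.06. Both chromosome 14 loci entered through calls that include the animal named, so the chance rate given above does not apply to them.

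The number of short regions per mouse was weighed against technical explanations, and no biological one was tested. Calls in genome order were 1.001 times those in shuffled probe order, which breaks up regions and keeps outlying probes, so isolated outlying probes may account for this number. The median over the 735 lower calls of the sire was -0.95 with the sire in Cy5 and -0.18 in Cy3. Over all tiles of the slide their chi-square per degree of freedom was 141.1. Of these calls 78.9% had their most extreme probe in the 7 tiles that were busiest for them. The 7 tiles hold 4.84% of the autosomal probes, a share that tiles picked this way exceed in any set of calls. These tiles form 3 separate groups, of which 4 adjoining tiles hold 68.4% of the calls, so damage on parts of that slide may account for the excess in the sire, and 77.1% of the 1861 probes called without the dam lie in the 7 tiles. Short real changes among the calls stay open, since counts cannot pick them out.

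For the levels of the chromosome 4 segment, a difference in the reference male alone is argued against by the SD between mice, 1.87 times the largest SD in 9997 random windows of as many probes. A dye effect is argued against by the dye control, at most 0.041 in size in any mouse, and scan batch by the dam and sire, which share a batch and differ by 0.44 against at most 0.21 in the windows. A possible explanation that stays open is 3 copies in the sire and progeny 1, 2, 5 and 6 and 4 copies in the dam and progeny 3 and 4, against 2 in the reference, where each mouse lies within 0.0865 of its predicted level, 0.51 or 0.88 on the scale of the X ratio of the dam. That distance was 0.0905 in the deposited value table, 0.124 with loess and 0.0386 without dim or marked probes. With normexp it was 0.389, since the X ratio of the dam then gives levels of 0.29 and 0.50 while the mice lie between 0.35 and 0.89, so the copy numbers depend on the processing.

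Loci carried by the dam and progeny 4, 5 and 6 made up 12 of 25, on 10 chromosomes. The 25 were called with 1 sign in the dam and a progeny and not with that sign in the sire. Independent transmission would give 0.397 (one-sided binomial p = 6.92e-14 after multiplying by the 63 possible sets of progeny). This argues against unlinked sites that the progeny inherited independently. Of the others among the 25, the dam shared 3 with progeny 5, 3 with progeny 5 and 6 and 3 with progeny 6. She shared 1 with progeny 4 and 1 with progeny 4 and 5, and all of these were lower. With progeny 1 to 3 among the carriers there was 1 of the dam and progeny 1 and 1 of the dam and progeny 2, 3, 5 and 6. Of the 12, 11 were lower than the reference and 9 rest on 1 probe. The 1 higher locus, on chromosome 8, holds a call of the opposite sign in the sire. Shuffled probe order gave 13 loci with these carriers, so the count is no evidence of regions. The same 4 mice have X ratios above 0.5, and sequence shared with the X or Y chromosome stays open as a possible explanation. Among 71 autosomal probes chosen by the dam alone, at -1 or below in both orientations, the medians were -1.17, -0.98 and -0.95 in progeny 4, 5 and 6 and 0.09, 0.04 and -0.18 in progeny 1, 2 and 3, so 6 of 6 progeny went with their X ratio. At -0.5 or below, 842 probes had medians of -0.05, -0.08 and -0.06 in progeny 4, 5 and 6 against -0.68 in the dam, so 3 of 6 progeny did. The 20 probes at 1 or above in the dam did not follow the X ratio, with medians of 0.52 in progeny 1 and 0.13 in progeny 4. They do not bear on sequence shared with the Y chromosome, whose ratio was lower than the reference in the dam and progeny 4, 5 and 6. Probe sequences were not compared with the sex chromosomes.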

How the results depend on the processing

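The settings of at least 30 probes, of calls that keep 0.25 without their most extreme probe and in each orientation, and of leaving out parents, or progeny from the counts of calls and of probe values, were chosen after seeing the data. The number of loci called in all 8 mice was 1 under every alternative run for it, and the chromosome 4 segment held calls in all 8 mice in each of the 11 settings in which the caller was run. The count of 1337 regions became 858 without dim or marked probes, 294 at a score of 8, 614 at 5 probes, 2028 in Cy5 alone, 790 in Cy3 alone, 222 for calls that keep 0.25 (223 in shuffled order, 397 in the dye control), 15 at 30 probes and between 553 (without the sire) and 1317 when each mouse was left out. The 243 candidate new loci became 111 with normexp and, in the order of the settings just named up to 30 probes, 71, 25, 103, 91, 80, 78 (80 in shuffled order) and 1, and 162 to 234 without each progeny. The 32 loci of parent and progeny became 10 at a score of 8, 18 at 5 probes, 4 for calls that keep 0.25 (1 in shuffled order), 2 at 30 probes and 26 to 33 without each progeny. Progeny minus parents, -353.2 calls, turned to 15.0 in Cy3 alone (exact permutation p = 0.607), the cause was not tested, and it lay between -705.2 and -1.17 when each mouse was left out. The 24149 probe values past the limit in both orientations became 2573 with normexp, 11132 without dim or marked probes, 163903 at a limit of 0.3 and 14228 to 22880 when each mouse was left out. The 26 probes of progeny against the reference became 6 with loess, 58 without dim or marked probes, 4 after a running median, 121773 in Cy5 alone, 31411 in Cy3 alone, 7 with scan batch as a block, and 0 to 55 without each progeny. In 1 orientation dye effects do not cancel. Progeny against parents gave 0 under every alternative fixed before the values were seen and 0 (without the sire) to 1861 (without the dam). The X ratio of the dam moved to 0.50 with normexp. Of the named loci 1 changed sign, on chromosome 18 at 65416939, to 0.077 without dim or marked probes. For the other changes the cause was not tested. No paired analysis was run, since all 6 progeny have the same 2 parents and replicate numbers only count animals within a group. Signal over background limits progeny 1 most, at 10.03 in green on 1 array. The planned gene lists were not run.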

Other observations

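The grouping on the slide was examined after the values were seen. On chromosome 14 a segment of 12 probes from 61799762 to 61819370 stood at -0.31 in the dam, -0.29 in progeny 4, -0.32 in progeny 5 and -0.25 in progeny 6, and between -0.11 and 0.06 in the other 4 mice. The carriers are the mice with X ratios above 0.5, so transmission and a difference that goes with sex are not told apart. Their means fall short of the -0.88 that 1 copy against 2 would give on the scale of the X ratio of the dam.

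Slide position was also uneven for the lower calls of progeny 2 and 6, with a chi-square per degree of freedom over the slide tiles of 9.24 and 3.26. The lower calls of the sire had 141.1, and the other sets of higher or lower calls had between 0.89 and 1.41.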
